A study of Sus scrofa domesticus with 4 samples.

How the data were processed

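Myometrial slices from pregnant gilts, in culture, were compared with and without orexin B on 4 Agilent pig arrays of 2 colours, with total RNA labelled as cRNA at 825 ng per dye, per the labels. The cultures were prepared in duplicate in 4 separate experiments with 4 gilts, per the labels; p-values measure the spread between these 4 arrays. The deposited scanner files hold spot intensity values, the median pixel brightness of each spot and of its local background in green (Cy3) and red (Cy5), made with Agilent Feature Extraction 10.7.3.1, per the file headers. The same files hold background-subtracted, dye-normalized intensity values and a log10 ratio of red over green, per the file headers, which the software sets to 0 for spots dim in both colours. The deposited series table holds log2 ratios. Set against each array's processed signals, 100% of its values matched the log2 ratio within 0.01 once the sign of arrays 2 and 4 was turned, with no further centring, and its column medians were -0.27, -0.08, -0.20 and -0.09. No genome build is named in the files, so no coordinates were used. No column of the table was left unmapped.

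The direction of each ratio came from the dye fields of each array's labels, which give untreated RNA in Cy3 on arrays 1 and 3 and in Cy5 on arrays 2 and 4. The protocol text in the labels names only the first orientation, and the plan fixed before the data were examined had assumed it for all arrays and no dye term. The ratios of arrays 2 and 4 were therefore turned, a departure from that plan, and Cy5 over Cy3 without turning was run as an added alternative. The plan also named mean spot signals; the median signals of the files were used.

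Background was corrected with normexp at an offset of 50, and each array was normalized by loess with control spots at weight 0, in R 4.3.3 with limma 3.58.1. Control spots and spots marked as non-uniform or population outliers (between 31 and 138 per array) were then left out, and spots of a probe were averaged. A probe was tested if it was well above background on all 4 arrays in the treated or in the untreated channel and had an unmarked spot on at least 3. This kept 19876 of 43603 probes. No probe was saturated. An intercept model was fitted to the turned log2 ratios with lmFit and eBayes (residual degrees of freedom 3, prior 4.10), and two-sided p-values were adjusted by Benjamini-Hochberg over all tested probes.

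The files give accessions and no gene names. RefSeq accessions were matched without version to the Sscrofa11.1 gene table, which 6700 probes matched, 6599 of them to a gene symbol. The other 37004 probes stayed unnamed. For gene lists and named genes, each gene was represented by its tested probe with the highest mean intensity, giving 1953 genes. Of 39 lists of genes and cell markers, 31 had at least 3 measured genes, and 8 smaller lists were not tested. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, all two-sided and adjusted over the 31 lists.

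The lists, tests, thresholds, other settings listed and the rule for named genes were chosen before the data were examined. The rule took the 12 highest and 12 lowest genes past the threshold with all arrays of the same sign; where under 5 genes in a direction passed, it took the 8 with the smallest p among those changed at least 1.2-fold with all arrays of the same sign. It added up to 4 members, smallest p first, of each list that passed, and 14 genes whatever their values, of which 10 were tested.

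The fit was tested on simulated ratios with the real spread of 19705 probes, of which 200 were changed. In this simulation of orexin B against untreated, an adjusted p under 0.05 was reached by 1.47% of probes changed by 0.5 on the log2 scale, 50.8% of those changed by 1 and 88.4% of those changed by 2. The alternatives covered background, normalization, filter, test, slide, channel pairing, source of the values and each array left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.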

Results

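The series asked how orexin B, a neuropeptide ligand of the orexin receptors, changes gene expression in the pig uterine muscle layer (myometrium) around the time of implantation. Slices of myometrium from gilts on days 15 to 16 of gestation were cultured for 24 h with 10 nM orexin B or without treatment. RNA of treated and untreated slices was hybridised together on 2-colour Agilent arrays, and 4 arrays were analysed, numbered 1 to 4 as replicates of a single group. The labels give 4 gilts for the 4 experiments. Orexin B RNA carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4. Every ratio below is orexin B over untreated on a log2 scale, with its moderated standard error over the 4 arrays. Of 43603 probes, 19876 were bright enough to test. The share of probes well above background in the treated channel was 54.2%, 48.7%, 51.2% and 52.7% on arrays 1 to 4. In the untreated channel it was 37.6%, 50.1%, 45.5% and 58.2%. The number of arrays limits the precision.

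Markers of macrophages and monocytes and interferon-stimulated genes were higher in explants cultured with orexin B, and genes of the smooth muscle contractile apparatus were lower, as gene lists under a test that assumes a small preset correlation between genes. None of the 3 kept its call with an estimated correlation (adjusted p = 0.661, 0.661 and 0.680 with an estimated correlation, in that order). The macrophage list had a median log2 ratio of 0.60, the interferon-stimulated list of 0.33 and the smooth muscle list of -0.49. No single probe passed an adjusted p of 0.05 in limma's moderated test (0 of 19876, smallest adjusted p = 0.596). At an unadjusted p under 0.05 there were 1534 probes, 7.72% of those tested against 993.8 expected by chance, of which 856 were higher and 678 lower; with median centring in place of loess 172 were higher and 5 lower. An unmoderated one-sample test on the same ratios also left 0 probes past the adjusted threshold and 1195 at the unadjusted one. With a change of at least 1.2-fold as well, limma gave 1528 probes, 853 higher and 675 lower, and 726 without replicate 4. With dye as a further term, chosen after seeing the data, limma left 0 probes past the adjusted threshold and 2382 at the unadjusted one for orexin B. For the dye term itself these counts were 0 and 2494. All 4 arrays had the same sign for 3181 probes, 16.0% of those tested, where chance gives 12.5%.

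Of 31 gene lists with at least 3 measured genes, 7 passed the preset-correlation test after Benjamini-Hochberg adjustment, 4 higher and 3 lower; without replicate 2 it was 3 lists and without replicate 4 it was 2. None of the 7 kept its call with a correlation estimated from the 4 arrays, and 0 lists passed limma's rotation test fry, which gave 2 lists at an unadjusted p under 0.05. The preset test in simulated lists with a between-gene correlation of 0.3 and no shift gave an unadjusted p under 0.05 in 39.0% of 200 runs of a 20-gene list drawn from 1953 genes, and the estimated correlation gave it in 2.5%. With a true shift of 0.3 and the same correlation, the preset test gave it in 195 of 200 runs and the estimated correlation in 53.5% of them. The correlation estimated from the 4 arrays was 0.86 for the smooth muscle list, 0.57 for macrophage, 0.48 for fibroblast and 0.41 for ribosomal genes. It was 0.37 for interferon-stimulated, 0.23 for antigen presentation and 0.10 for inflammatory genes. The simulation was not run at these values, so 39.0% is not the false-call rate of these lists.

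**Figure D1:**
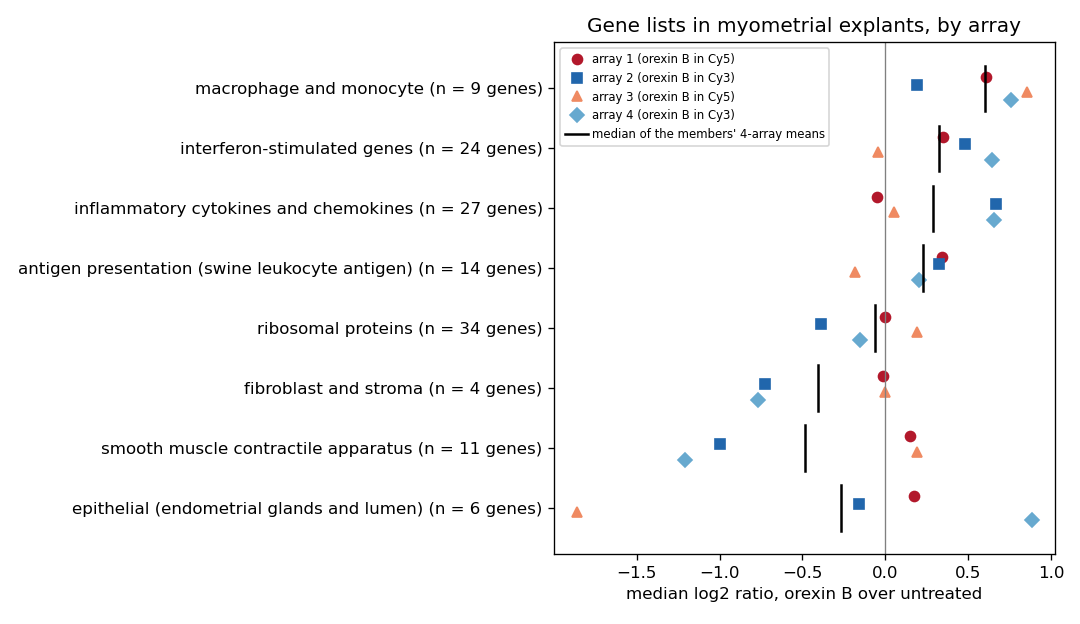
Median log2 ratio of orexin B over untreated (x axis) for the 7 gene lists that passed the preset-correlation test and for the epithelial list (y axis, with the number of measured genes). Points are single arrays, coloured by the dye on the orexin B RNA, and black lines are the median over members of their 4-array means; the smooth muscle medians lie at 0.15 and 0.19 on arrays 1 and 3 and at -0.998 and -1.21 on arrays 2 and 4.

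All 9 measured macrophage and monocyte markers had a mean above 0, and 8 of them passed adjusted over the list alone, against 0 over all probes tested. AIF1, a calcium-binding protein of macrophages, had a log2 ratio of 0.63 ± 0.14, and C1QB, a chain of complement C1q made largely by macrophages, had 0.98 ± 0.24. FCER1G, an Fc receptor signalling chain, had 0.51 ± 0.15, and CD163, a scavenger receptor, had 0.60 ± 0.18. CD14, the lipopolysaccharide co-receptor, had 0.08 ± 0.18. The list's medians on arrays 1 to 4 were 0.61, 0.19, 0.86 and 0.76 (adjusted p = 1.58e-06 with the preset correlation, adjusted p = 0.661 with an estimated correlation). Of the 9 markers, 3 also belong to another list, the C1q chains of the complement list.

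Of 24 interferon-stimulated genes, 22 had a mean above 0, and 1 passed adjusted over the list alone, against 0 over all probes tested. IFIT3 had a log2 ratio of 1.36 ± 0.28, RSAD2 (viperin, an antiviral enzyme) 1.56 ± 0.45, the RNA sensor IFIH1 0.96 ± 0.24 and USP18, which removes ISG15 from proteins, 0.50 ± 0.14. The list's medians were 0.35, 0.48, -0.04 and 0.64 on arrays 1 to 4 (adjusted p = 1.58e-06 with the preset correlation, adjusted p = 0.661 with an estimated correlation). The median was 0.50 without replicate 3 and 0.21 with median centring in place of loess. Array 3, where this list was lowest, had the highest macrophage median, 0.86, and an epithelial marker median of -1.86, against 0.17, -0.16 and 0.88 on arrays 1, 2 and 4.

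Antigen presentation genes (swine leukocyte antigen, 14 measured, 13 above 0) had a median of 0.23 and array medians of 0.34, 0.33, -0.18 and 0.20, with 0 members past adjusted over the list alone. SLA-3, a class I gene, had 0.39 ± 0.12, SLA-5 0.37 ± 0.16, CD74, the class II invariant chain, 0.29 ± 0.13, and SLA-DRA 0.55 ± 0.26. SLA-DRA was 0.27 without replicate 2 and 0.85 without replicate 3, SLA-5 was 0.21 without replicate 4, and SLA-3 and SLA-5 were 0.21 and 0.20 with median centring. The adjusted p was 0.0194 with the preset correlation and adjusted p = 0.661 with an estimated correlation. The call ended with median centring (adjusted p = 0.0622) and without replicate 1, 2 or 4 (medians 0.13, 0.14 and 0.20, adjusted p 0.0992, 0.387 and 0.0514), and without replicate 3 the median was 0.45. Macrophages also carry class II molecules, and their markers had a median of 0.60. Inflammatory cytokines and chemokines (27 measured, 22 above 0) had a median of 0.29, with 0 members past adjusted over the list alone. The neutrophil chemoattractant CXCL8 had 1.66 ± 0.55, IL1A 0.95 ± 0.35, the adhesion molecule ICAM1 0.46 ± 0.14 and the granulocyte growth factor CSF3 0.48 ± 0.20. This list's medians were -0.05 and 0.05 on arrays 1 and 3 and 0.67 and 0.65 on arrays 2 and 4, which differ in dye orientation (adjusted p = 0.0242 with the preset correlation, adjusted p = 0.661 with an estimated correlation). The call ended without replicate 2 (median 0.22, adjusted p = 0.564) and without replicate 4 (median 0.13, adjusted p = 0.192). CXCL8 ranged from 0.42 on array 1 to 3.97 on array 4, and its mean was 0.89 without replicate 4. Without the same replicate CSF3 was 0.27, and without replicate 2 IL1A was 0.59. Neutrophil markers (3 measured) had medians of 0.14, 0.68, -0.11 and 0.60.

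All 11 measured genes of the smooth muscle contractile apparatus had a mean below 0, and 0 passed over all probes or adjusted over the list alone. CNN1 (calponin) had a log2 ratio of -0.61 ± 0.26, MYLK (myosin light chain kinase) -0.65 ± 0.28, SMTN (smoothelin) -0.51 ± 0.26 and MYL6, a myosin light chain, -0.38 ± 0.21. DES (desmin) had -0.49 ± 0.30 and ACTA2 (smooth muscle actin) -0.49 ± 0.40. Without replicate 4 CNN1 was -0.40, MYLK -0.34, SMTN -0.21, DES -0.28 and ACTA2 -0.049. Without replicate 2 CNN1 was -0.40, MYL6 -0.19, DES -0.27 and ACTA2 -0.27, and without replicate 3 DES was -0.88 and ACTA2 -0.90. The list's medians were 0.15 and 0.19 on arrays 1 and 3 but -0.998 and -1.21 on arrays 2 and 4, so that the mean below 0 came from the arrays with orexin B RNA in Cy3 (adjusted p = 2.02e-04 with the preset correlation, adjusted p = 0.680 with an estimated correlation). Without replicate 4 the median was -0.24 and the adjusted p 0.0991, and without replicate 2 they were -0.27 and 0.0170. Fibroblast and stroma markers (4 measured, all below 0) followed the same arrays, with medians of -0.016, -0.72, -0.0016 and -0.77, a list median of -0.41 and 0 members past adjusted over the list alone. Their examples were DCN (decorin, -0.43 ± 0.13), LUM (lumican, -0.44 ± 0.20), COL1A2 (-0.39 ± 0.25) and CD34 (-0.23 ± 0.18), with adjusted p = 0.0160 with the preset correlation and adjusted p = 0.661 with an estimated correlation. Without replicate 4 LUM was -0.27 and COL1A2 -0.15, without replicate 2 COL1A2 was -0.23 and CD34 -0.096, without replicate 3 COL1A2 was -0.62 and without replicate 1 CD34 was -0.44. The fibroblast call ended with median centring (adjusted p = 0.0550), without replicate 2 (median -0.27, adjusted p = 0.103) and without replicate 4 (median -0.23, adjusted p = 0.0991). Of the 4 fibroblast markers, DCN, LUM and COL1A2 also belong to the extracellular matrix list. That list (24 measured, 12 above and 12 below 0) had a median of 0.03. It did not pass (adjusted p = 0.770 with the preset correlation).

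Ribosomal protein genes (34 measured, 26 below 0) had a median of -0.06, with array medians of -0.0027, -0.39, 0.19 and -0.15 and 0 members past adjusted over the list alone. RPL13A had -0.47 ± 0.17, RPS10 -0.31 ± 0.16, RPL14 -0.23 ± 0.14 and RPL11 -0.24 ± 0.15 (list adjusted p = 0.0413 with the preset correlation, adjusted p = 0.836 with an estimated correlation). Without replicate 1 RPS10 was -0.17 and RPL14 -0.11, without replicate 3 RPL11 was -0.39, and with median centring RPL14 and RPL11 were -0.39 and -0.38. The call ended without background correction (adjusted p = 0.0560), with Agilent's processed ratio (0.101), with the series table (0.109), with the strict filter (0.0565) and without replicate 1, 2 or 4 (medians -0.10, 0.03 and -0.06, adjusted p 0.0644, 0.694 and 0.226), and the median was -0.15 without replicate 3 and -0.21 with median centring (adjusted p = 0.0176). The fibroblast, smooth muscle and ribosomal lists were each lowest on arrays 2 and 4. The ribosomal array medians had a mean of 0.095 with orexin B in Cy5 and -0.27 with it in Cy3. Among random lists matched on intensity, the ribosomal list lay at percentile 6.69, so a bias of spots of that brightness stays open for it. The percentile was 0.15 for fibroblast, 99.87 for antigen presentation and 100 for inflammatory genes.

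Among single genes that did not pass the threshold (adjusted p = 0.596 for all 16), the 8 with the smallest p in each direction and 4 arrays of the same sign were chosen by a rule fixed beforehand. The higher genes were PTBP1, an RNA-binding splicing regulator (0.79 ± 0.11), the membrane protein EMP1 (1.03 ± 0.17), CALR, a chaperone of the endoplasmic reticulum (0.74 ± 0.13), the platelet chemokine PPBP (1.14 ± 0.20), the histone gene HIST1H2BD (0.58 ± 0.12), IFIT3, the fatty acid binding protein FABP5 (0.74 ± 0.15) and AIF1. PPBP was 2.20-fold and EMP1 2.05-fold higher; in the untreated channel PPBP was well above background on 3 of the 4 arrays. The lower genes were DDO, the oxidase of D-aspartate (-0.58 ± 0.12), complement factor B, CFB (-0.79 ± 0.16), ADIRF (-0.78 ± 0.18), DTNBP1 (-0.45 ± 0.11), the peptidase APEH (-0.52 ± 0.13), the forkhead factor FOXN3 (-0.46 ± 0.11), the co-chaperone DNAJB1 (-0.76 ± 0.19) and ATP9A (-0.52 ± 0.13). CFB was 1.73-fold lower and DNAJB1 1.69-fold lower. DDO was -0.98 and DTNBP1 -0.75 with Agilent's processed ratio and with the series table. Of 52 named genes, 29 had further tested probes, which all had the same direction for 27; FOXN3 and RPL14 had a probe that went the other way.

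**Figure D2:**
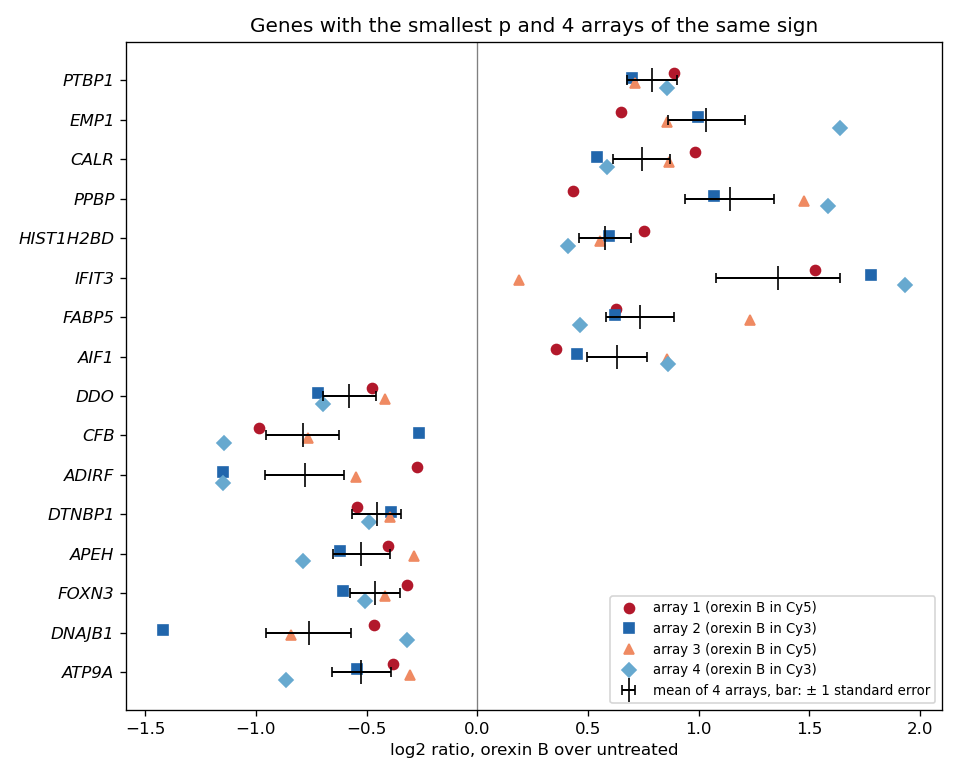
Log2 ratio of orexin B over untreated (x axis) for the 16 genes with the smallest p among those with 4 arrays of the same sign (y axis). Points are single arrays, vertical ticks the mean of 4 arrays and bars ± 1 moderated standard error; IFIT3 runs from 0.19 on array 3 to 1.93 on array 4, and PTBP1 lies between 0.70 and 0.89.

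The orexin system itself was largely below background. HCRT, the precursor of orexins A and B, had a log2 ratio of 0.03 ± 0.13 and was well above background on 3 of the 4 arrays in the untreated channel. The receptor genes HCRTR1 and HCRTR2, and PTGFR, the prostaglandin F receptor, were well above background on 0 of 4 arrays in either channel, so no ratio was given for them. MYH11 was not analysed here. Of contraction-associated genes, the oxytocin receptor OXTR had 0.16 ± 0.13 and the gap junction gene GJA1 0.31 ± 0.13 (adjusted p = 0.645, all 4 arrays above 0). The prostaglandin synthases PTGS2 and PTGES had 0.64 ± 0.43 and 0.11 ± 0.13, and PTGS2 was at -1.23 on array 3 against 1.51, 0.95 and 1.32 on arrays 1, 2 and 4. The steroid receptors ESR1 and PGR had 0.31 ± 0.12 (all 4 arrays above 0) and -0.14 ± 0.22, and the immediate early gene FOS had -0.17 ± 0.28. None of these passed the threshold over all probes. Without 1 replicate OXTR ran from 0.093 to 0.26, PTGS2 from 0.35 to 1.26, PTGES from -0.0066 to 0.16, HCRT from -0.047 to 0.11, PGR from -0.33 to 0.036 and FOS from -0.44 to 0.17.

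The other 24 lists did not pass. Their medians ran from -0.26 for 6 epithelial markers to 0.49 for 3 conceptus trophoblast markers, and the smallest adjusted p was 0.0615, for angiogenic ligands and receptors (10 measured, median 0.14, arrays 0.17, 0.10, 0.21 and 0.13). Blood endothelium markers (4 measured) had a median of 0.31 and T and NK cell markers (5 measured) of 0.24. Contraction-associated receptors and channels (11 measured) had a median of -0.05, prostaglandin genes (6 measured) of 0.11 and steroid synthesis genes and receptors (16 measured) of -0.01. In the heat shock and unfolded protein list (16 measured, median 0.02), 2 members passed adjusted over the list alone and 0 over all probes. The complement and coagulation list (23 measured, median 0.01) and the lipid metabolism list (22 measured, median -0.01) each had 1 such member.

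Across probes, which are not independent replicates, the log2 ratios of arrays with the same dye orientation correlated at r = 0.14 (arrays 1 and 3) and r = 0.36 (arrays 2 and 4). Pairs of swapped orientation had r of 0.04, 0.14, -0.18 and -0.04, a mean of -0.01. A dye effect raises r within an orientation and lowers it between orientations. Arrays 2, 3 and 4 shared a slide, and array 1 was alone on another; on the shared slide r ran from -0.18 to 0.36, and the 3 arrays alone gave 0 probes past the threshold and 5 lists past the preset test. Different probes of a gene followed each other: over 963 genes with at least 2 tested probes, the brightest and second brightest had a Spearman rho of 0.76 and a Pearson r of 0.77 across genes, with the same direction for 79.96%.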

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

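The dye tests of all 3 lists, the macrophage RNA test, and the sign splits of the lists and of the unadjusted counts were chosen after the result was seen; the other tests were set before their result was seen. Of 86 sets of 4 array values examined for a value far from the rest, 1 was found where chance gives 4.3. RPL11, a ribosomal protein gene, had a log2 ratio of 0.22 on array 3 and between -0.43 and -0.37 on the other arrays.

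The smooth muscle contractile list was lower with orexin B on arrays 2 and 4 only. A dye effect of the same size on every array as the whole cause was argued against. The treatment part beside a dye term was -0.47 ± 0.05 (standard error, 2 residual degrees of freedom). This lay 8.62 standard errors from 0 against a 95% bound of 4.303. That standard error holds only once the difference between orientations is assigned to dye. Without that step the 4 array medians had an SD of 0.74 around their mean of -0.47. The rotation test fry gave an unadjusted p of 0.299 for the list. The list lay at percentile 0 of intensity-matched random lists on arrays 2 and 4, and at 93.2 and 93.4 on arrays 1 and 3. The test used only arrays 2 and 4, where the list was already seen to be low. The random lists were drawn without the list's correlation of 0.86. The percentiles therefore argue against a bias shared by all spots of that brightness, but do not measure chance. The mean of the list's medians was 0.17 on the arrays with orexin B in Cy5 and -1.10 on the others. An equal dye effect of 0.64 beside the treatment part gives these values. A dye effect that differs between arrays stays open. The SD of log2 ratios over tested probes was 0.31 and 0.33 on arrays 1 and 3 and 0.52 and 0.42 on arrays 2 and 4. Agilent's RMS value for its dye normalization was 0.21 and 0.25 against 0.47 and 0.42. A dye effect that differed by orientation in this way cannot be told apart from treatment by the design. A lower share of muscle in the treated slices of those experiments may also be the source and was not tested.

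The macrophage and monocyte list was above 0 on each array. Its lowest median was 0.19, and the orientation means were 0.73 with orexin B in Cy5 and 0.47 with it in Cy3. An equal dye effect has opposite signs in the orientations and cancels in their mean, 0.60 ± 0.15, so it cannot give that mean. The dye part beside it was 0.13 ± 0.15. The mean lay 3.91 standard errors from 0, short of the bound of 4.303 for 2 degrees of freedom. The spread between arrays therefore stays open as its source. Its percentile of 100 among intensity-matched lists argues against a bias of spots of that brightness. More macrophage RNA with orexin B and slices that differ in their cell makeup without regard to treatment also stay open. The camera p of 0.0973, before adjustment, with an estimated correlation does not separate them. Macrophage counts in sections of the same explants were not used here.

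The interferon-stimulated list was higher on 3 arrays. Its lowest median was -0.043, on array 3. Both orientation means were above 0 (0.15 and 0.56). An equal dye effect cancels in their mean of 0.36 ± 0.11, so it cannot give that mean. The dye part beside it was -0.21 ± 0.11. The mean lay 3.40 standard errors from 0, short of the same bound of 4.303, so the spread between arrays stays open as its source. Its percentile of 100 among intensity-matched lists argues against a bias of spots of that brightness. The array medians did not follow those of macrophage markers on array 3 (0.86 for macrophage markers, -0.043 here) or array 2 (0.19 and 0.48), while array 4 was high in both (0.76 and 0.64). With 4 arrays, more macrophage RNA stays open.

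The 4 arrays allow 8 sign splits, too few for a share under 0.05. For probes past the adjusted threshold, 8 of the 8 splits gave as many, with a real count of 0 and 0 as the highest other. For probes at unadjusted p under 0.05 and 1.2-fold, 3 of the 8 splits gave as many, with 1528 in the real split and 1632 as the highest other, the split that sets Cy5 against Cy3 on every array. For lists past the preset test, 2 of the 8 splits gave as many, with 7 in the real split and 8 as the highest other. The other splits that gave as many probes or lists set the dyes unequally and so hold any dye effect. The split with 1547 probes and 8 lists turned array 3 alone, so dye and array 3 cannot be told apart in it. The splits balanced for dye besides the real one gave 273 and 454 probes and 1 and 4 lists. The balanced splits are fewer than 8 and likewise allow no share under 0.05. Bias of single probes was argued against, for tested probes as a whole, by the rho of 0.76 between probes of a gene. It was at least 0.66 without any 1 array. Since 0 probes passed the threshold, the rho bears on no called probe. Any difference that moves all probes of a transcript would give it, whether or not orexin B was the source. An array that stands apart could not be judged from counts past the threshold, since the highest count without an array was 0.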

How the results depend on the processing

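The dye term, the unturned ratios and the medians per dye orientation were chosen after seeing the data. Counts past the adjusted threshold were 0 under each setting run, with the smallest adjusted p (0.0784) with slide as a random block. In that setting the correlation within a slide was estimated at -0.26, from 1 slide with 3 arrays and 1 with a single array. A negative value lowers the standard errors. The 1528 probes at unadjusted p and 1.2-fold became 177 with median centring instead of loess, 675 with an unmoderated test, 3372 with slide as a random block, 494 from single channels with no replicate block, 341 at 1.5-fold, 2372 with a dye term, and 726 (without replicate 4) to 1922 without 1 replicate. With the array as replicate block, single channels gave 1528, as their construction requires. The 55.8% share higher became 97.2% with median centring (172 higher, 5 lower), 60.3% with Agilent's processed ratio, 60.4% with the series table, 52.4% with no filter, 58.5% with trend and robust eBayes, 61.8% on the slide with 3 arrays, 65.4% from single channels, 50.8% unturned, and 55.7% to 62.3% without 1 replicate. The 7 lists became 0 with an estimated correlation, 0 with fry, and 2 (without replicate 4), 3 (without replicate 2) to 7 without 1 replicate. Unturned, medians changed sign for smooth muscle (0.63), inflammatory (-0.42), interferon-stimulated (-0.25), antigen presentation (-0.12), ribosomal (0.16) and fibroblast (0.36) lists. Over members' means on the arrays with orexin B in Cy5 alone, smooth muscle (0.16), ribosomal (0.074) and fibroblast (0.023) lists lay above 0. HCRT was -0.026 with Agilent's ratio, -0.026 with the series table and -0.047 to 0.11 without 1 replicate; PTGES was -0.017 with median centring and -0.0066 to 0.16 without 1 replicate; PGR ran from -0.33 to 0.036 and FOS from -0.44 to 0.17 without 1 replicate. Mean r between arrays was -0.08 with median centring. Apart from the single-channel block and the changes of dye direction, the cause was not tested. Dim signal kept 23725 probes, the orexin receptors among them, out of the test, and too few unmarked spots 2 more.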

Other observations

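The tests here were planned, and the choice of features was made after their values were seen. Epithelial markers of glands and lumen differed most between experiments among the 31 lists, with medians of 0.17, -0.16, -1.86 and 0.88 on arrays 1 to 4 (SD 1.16, 6 genes). On array 3, the experiment with that lowest epithelial median, PTGS2 was at -1.23, antigen presentation genes at -0.18 and T and NK cell markers at 0.57, against 0.02, 0.15 and 0.08 for the T and NK cell list on arrays 1, 2 and 4.

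Angiogenic ligands and receptors had array medians above 0 on 4 of 4 arrays, from 0.10 to 0.21, in both dye orientations. The rotation test gave an unadjusted p of 0.00681 and an adjusted p of 0.211 over the 31 lists.

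Among unnamed probes, the transcripts AJ663178 and TC570031 had log2 ratios of 0.87 ± 0.12 and 0.68 ± 0.11, above 0 on each array. Both probes of transcript EW646562 were below 0 on each array, at -0.90 ± 0.12 and -0.82 ± 0.13. Their adjusted p in limma was 0.596.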
